A study of Homo sapiens with 6 samples.

How the data were processed

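Expression was measured on Affymetrix human arrays of 54675 probe sets in 6 samples of the HT-29 colon adenocarcinoma line. The 3 cell variants were wild type, BR100 and BR200, with 2 arrays each. One array of each variant was made from 100 ng of total RNA with the 3' IVT Express labelling kit (replicate 1) and the other from 3 ug with the One-Cycle kit (replicate 2). Per the labels, HT-29 cells had been grown in bortezomib, a proteasome inhibitor, raised in steps from 20 to 300 nM over 7 months, and clones were then taken by 2 limiting dilutions under 100 or 300 nM for 4 more months. The same treatment text stands on every sample, wild type included. It gives neither the dose under which BR200 was cloned nor whether the drug was present when any variant was harvested. The labels do not say that the arrays of a variant came from separate cultures, so every p-value here measures only the spread between these arrays.

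The values were deposited by the authors as log2 expression, 1 per probe set, made with GCRMA, which corrects for background, normalizes and summarizes the probes; its version was not given. All 6 arrays shared a lowest value of 2.23, which 34.8% to 35.3% of the probe sets of an array held. No detection calls were given. Signal over that background, and the number of arrays, limit the precision.

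Probe sets were assigned to genes from the array's annotation table. Its symbols were checked through gene identifiers against the RefSeq annotation of GRCh38.p14, and none differed among the 41043 probe sets matched. The annotation named 1 gene for 41097 probe sets, several for 1801 and none for 11777; the last 2 kinds were left out of the gene tests. Each of 19775 genes was represented by the probe set with the highest mean among those naming that gene alone. Genes were kept where at least 2 of the 6 arrays reached a log2 value of 4, which left 10370 genes and set 9405 aside. A gene under 4 on both arrays of a variant is called near background there, and its fold change depends on the background estimate.

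The 3 comparisons of variants came from a single linear model over all 6 arrays with a term for variant and a block for labelling kit, fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3. The test was two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes kept. The model had 2 residual degrees of freedom, to which eBayes added 2.33 from the other genes. Errors of fold changes are limma's standard errors (SE), and errors of levels are SDs over the 2 arrays. The kit comparison used the same model with the variants as the block. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 of 33 lists that had at least 4 tested genes. Camera with an estimated correlation and fry were run beside it. The estimated form rests on the 2 residual degrees of freedom, which left it little power to call any list. Its median estimated correlation was 0.0213, and its smallest unadjusted p over the 3 comparisons was 0.0265. For each list, genes were also counted with the p-values adjusted over the list alone.

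The comparisons, filter, gene lists, alternatives (but 1, the split of the controls) and rule for naming genes were fixed before the data were examined. The rule takes, for each comparison, the 10 largest rises and 10 largest falls among called genes with the same direction in both kits. It adds the 8 genes that rose most and the 8 that fell most in both resistant variants, ranked by the smaller change, up to 4 called members of each list with the largest change, and 14 genes whatever their values (PSMB5, PSMB1, PSMB2, POMP, ABCB1, HSPA5, HSPA1A, DDIT3, SQSTM1, BCL2L1, MCL1, PMAIP1, XBP1 and NFE2L1). Text examples were taken by rank; a list member outside the rule was chosen after its values were seen. The lists covered the proteasome (20S core, 19S regulator, immunoproteasome with the 11S cap, assembly factors and alternative caps), ubiquitin conjugation, stress responses, cell death, cell cycle, drug efflux, inflammation, epithelial, mesenchymal and intestinal states, metabolism, ribosomes and metallothioneins. Short lists of fibroblast, blood cell and endothelial markers were included to look for other cells and had too few tested genes for camera.

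The model was tested on simulated data with the design of BR100 against wild type. In 10 simulations with 200 changed genes among 10370, the model recovered 71.8% of genes changed 1.5-fold, 97.5% of those changed 2-fold and 100% of those changed 4-fold, with a mean of 13.6 false calls among 10170 unchanged genes. The shifted list had an unadjusted p under 0.05 in 10 of 10 simulations, as did 1.1% of 1000 unshifted lists, 100 per simulation. Simulated noise was independent between genes, so these list rates do not bear on correlated genes. Far fewer genes were changed than were called in the data against wild type, so recovery and false calls may not carry over.

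Alternatives left out the kit block or the filter, raised the filter to 6, set values under 4 to 4, applied quantile normalization or median centring, averaged the probe sets of a gene, left out probe sets marked as cross-hybridizing or shared between transcripts, and tested each probe set on its own. Others used an intensity trend or robust eBayes, fitted only the variants compared, required a 2-fold change, took each kit alone, and left out each array in turn. The controls were split between the resistant variants for the correlation of fold changes, an alternative chosen after seeing the data. Positions of genes along chromosomes came from the RefSeq annotation of GRCh38.p14. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets of control sequences were used only to compare 3' with 5' signal and the labelling kits.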

Results

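Gene expression was compared between 3 variants of HT-29, a human colon adenocarcinoma line. BR100 and BR200 came from cells grown for months in bortezomib, a drug that blocks the proteasome, and the third variant was labelled wild type. Each variant had 2 arrays, 1 per labelling kit. Between 10063 and 10193 genes reached a log2 value of 4 on an array. Across genes, the arrays of a variant correlated at r = 0.983 to 0.985 between kits. BR100 correlated with BR200 at r = 0.986 to 0.987 within a kit, and wild type correlated with either resistant variant at 0.891 to 0.904; genes are not independent replicates, so no p is given. The 3' minus 5' gap of ACTB, a measure of RNA integrity and of labelling, was larger in wild type (3.61 on the log2 scale, mean of 2 arrays) than in the resistant variants (2.47, mean of 4 arrays). That gap also differed between the kits, by 1.29 (Express minus One-Cycle). The same gap of GAPDH was 0.44 in wild type and 0.19 in the resistant variants.

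The series asks how expression differs between the variants, and the first comparison set BR100 against wild type. Proteasome subunits, DNA replication genes and cholesterol synthesis genes were higher in BR100, and genes of the ATF4 amino acid response and interferon-stimulated genes were lower. With an estimated correlation between genes none of these lists kept its call (adjusted p = 0.363 to 0.372). That form of the test rests on 2 residual degrees of freedom and had little power to call any list. PSMB5, the catalytic subunit that bortezomib binds, rose from 10.57 ± 0.26 to 12.26 ± 0.26 (log2, SD, n = 2 each), a 3.22-fold increase (log2 change 1.69, SE 0.0664, adjusted p = 0.000166). MCM10, a replication factor, rose by 5.60 (SE 0.0836) from near background. CHAC1, an ATF4 target that degrades glutathione, fell by 6.13 (SE 0.0647) to near background.

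Of 13 measured genes of the 20S core, 12 rose in BR100 and 1 did not pass, with a median log2 change of 1.005 (camera adjusted p = 0.000757 and adjusted p = 0.372 with an estimated correlation). PSMA3 rose by 1.55, PSMB2 by 1.46 and PSMB6 by 1.19, and PSMB1 was at −0.00 (adjusted p = 1). Among 16 genes of the 19S regulator, 14 rose and 1 fell (median 0.85, adjusted p = 0.00186 and adjusted p = 0.372 with an estimated correlation). PSMC1, PSMD1, PSMD12 and PSMD11 changed by 1.45, 1.38, 1.27 and 1.20. The PSMD11 value was −0.12 without cross-hybridizing or shared probe sets. PSMD2 was the member that fell, by 0.61. PSMB5, PSMA3, PSMC1 and PSMC6 lie on chromosome 14, whose genes were higher as a group in both resistant variants. POMP, a 20S assembly chaperone, rose by 0.38, while NFE2L1, a transcription factor of proteasome genes, fell by 1.82. The assembly and alternative cap list had 8 risers and 2 fallers among 13 (median 0.38, adjusted p = 0.186) and included PSMG1 at 1.53. In the ubiquitin list 8 of 15 rose and 4 fell (median 0.22, adjusted p = 0.42), with VCP at 1.51 and UBA1 at 1.31.

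Genes of the ATF4 and unfolded protein responses were lower in BR100, and metallothioneins were higher, calls that were lost with an estimated correlation. All 24 measured genes of the ATF4 list fell (median −3.10, adjusted p = 4.92e-12 and adjusted p = 0.363 with an estimated correlation), among them NUPR1 at −5.08, SESN2 at −4.62 and VLDLR at −4.46. DDIT3, which encodes the stress factor CHOP, fell by 3.65. Of 21 unfolded protein response genes, 13 fell and 3 rose (median −0.64, adjusted p = 0.0069 and adjusted p = 0.363 with an estimated correlation). ERN1, the endoplasmic reticulum stress sensor, fell by 3.64, HERPUD1 by 2.85, XBP1 by 1.34 and the chaperone HSPA5 by 0.86. Heat shock genes counted 9 higher and 2 lower of 15, a list not past the threshold (median 0.63, adjusted p = 0.0845), and HSPB1 rose by 3.21. HSPA1A, HSPA1B and HSPA8 of that list had no probe set of their own, and HSPB8 and CRYAB were below the filter. All 6 metallothioneins rose (median 0.87, adjusted p = 0.01 and adjusted p = 0.363 with an estimated correlation), MT1F by 1.13 and MT1X by 0.93. The NRF2 list split into 7 higher and 9 lower of 18 (median −0.23, adjusted p = 0.444), and the aldo-keto reductases AKR1B10 and AKR1C1 fell by 3.97 and 2.54. Autophagy genes also split, 7 higher and 10 lower of 22 (median −0.39, adjusted p = 0.176). MAP1LC3B fell by 3.06, ULK1 by 2.60 and SQSTM1, the p62 receptor, by 1.06.

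DNA replication genes showed the highest list median in BR100: 29 of 31 rose (median 3.04, adjusted p = 2.23e-11 and adjusted p = 0.363 with an estimated correlation). POLE2 rose by 5.27, CCNE2 by 5.20 and GINS2 by 4.83, and E2F1 and RFC5 did not pass, at 0.14 and −0.01. G2/M and mitosis genes rose less, 23 of 28 with 1 faller (median 0.64, adjusted p = 0.000153 and adjusted p = 0.372 with an estimated correlation), and included CDC20 at 1.89, MAD2L1 at 1.70 and MKI67 at 1.43. In metabolism, all 13 cholesterol synthesis genes rose (median 1.76, adjusted p = 3.42e-05 and adjusted p = 0.363 with an estimated correlation), with FDPS at 2.74, HMGCS1 at 2.53 and INSIG1 at 2.52. Of 25 respiratory chain genes, 20 rose and none fell (median 0.58, adjusted p = 0.000757 and adjusted p = 0.363 with an estimated correlation). NDUFA9 rose by 1.73 and NDUFB8 by 1.59. SDHC was at 1.47, or at −0.37 without cross-hybridizing or shared probe sets. Glycolysis genes were higher in 14 of 19, including GPI at 1.44 (median 0.44, adjusted p = 0.0172 and adjusted p = 0.417 with an estimated correlation), and the faller was the glucose transporter SLC2A1 at −1.66. Hypoxia response genes fell in 12 of 15 and rose in 3 (median −1.02, adjusted p = 0.00964 and adjusted p = 0.363 with an estimated correlation). NDRG1 fell by 5.56 and VEGFA by 3.11, and HILPDA rose by 1.81.

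All 24 interferon-stimulated genes fell in BR100 (median −3.47, adjusted p = 4.92e-12 and adjusted p = 0.363 with an estimated correlation): IFI44L at −8.46, XAF1 at −7.29, MX2 at −6.31 and MX1 at −5.97. IFI44L, XAF1 and MX2 fell to near background, so the size of their falls depends on the background estimate. MHC class I genes fell in 7 of 10 and rose in 2 (median −0.64, adjusted p = 0.0332 and adjusted p = 0.372 with an estimated correlation); the peptide transporter genes TAP2 and TAP1 fell by 2.42 and 1.68. The immunoproteasome list did not shift, with 2 higher and 1 lower of 4 (median 0.22, adjusted p = 0.788). Epithelial adhesion genes fell in 8 of 20 and rose in 2 (median −0.22, adjusted p = 0.0174 and adjusted p = 0.372 with an estimated correlation). CLDN1, which lies in a chromosome 3 block of lower genes, fell by 3.32 and CLDN7 by 1.52, while CLDN2 rose by 0.98. NF-kappaB targets split into 6 higher and 4 lower of 12 (median 0.50, adjusted p = 0.566), with the chemokine CXCL8 at 4.86 and CXCL2 at −2.57.

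The cell death, p53, efflux, mesenchymal, intestinal and ribosome lists did not pass in BR100. Anti-apoptotic genes had 2 higher and 5 lower of 10 (median −0.31, adjusted p = 0.218). BIRC5 rose by 0.94, BCL2L1 fell by 0.85 and MCL1 by 0.48, although MCL1 was at 0.20 when its probe sets were averaged. Pro-apoptotic genes had 6 higher and 7 lower of 20 (median 0.01, mean −0.16, camera direction down, adjusted p = 0.788), including TNFRSF10B at −2.51, TNFSF10 at −2.48, PMAIP1 at −2.18 and BAX at 1.82. Of 15 p53 targets, 3 rose and 8 fell (median −0.79, adjusted p = 0.0845), with DDB2 at 4.04 and GDF15 at −2.93. Among 7 efflux transporters 3 rose and 2 fell (mean −0.015, camera direction up, adjusted p = 0.932). MVP fell by 2.01, ABCG2 rose by 1.88, ABCC3 fell by 1.59, and ABCB1 stayed at the lowest value of 2.23 on every array. Mesenchymal genes had 4 higher and 5 lower of 9 (median −0.56, mean 0.06, camera direction down, adjusted p = 0.745), with FN1 at 4.13 and TNC at −3.58. Enterocyte genes had 2 higher and 5 lower of 8 (median −1.20, adjusted p = 0.166), with CEACAM6 at −4.07 and CA2 at 3.18, and goblet genes had 2 higher and 4 lower of 9 (median −0.13, adjusted p = 0.294), with TFF1 at −5.07. The intestinal stem cell and Wnt list had 4 higher and 5 lower of 11 (median 0.25, mean 0.10, camera direction down, adjusted p = 0.913), with DKK1 at 3.48. Of 22 ribosomal protein genes 4 rose and none fell (median 0.05, adjusted p = 0.745). Few markers of other cell types were above the filter: 3 fibroblast genes (TAGLN at −1.10, ACTA2 at 1.02, COL1A1 at −0.33), 2 blood cell genes, neither past the threshold (CD14 at 0.26, LYZ at 0.17), and ENG for endothelium at −0.02.

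The single genes that changed most in BR100 included TM4SF4, a membrane protein, which fell by 10.38 (SE 0.0664) to near background. LAMP3 fell by 8.87 (SE 0.469), UNC5B by 8.43 (SE 0.358) and CLGN by 8.21 (SE 0.0888), also to near background, and NIBAN1 fell by 8.35 (SE 0.150). ASS1, the argininosuccinate synthase gene, fell by 8.11 (SE 0.274). PHACTR3 rose by 6.01 (SE 0.0726) and the anion transporter SLC26A9 by 5.62 (SE 0.119), both from near background, and ELF5 rose by 5.50 (SE 0.239). limma called 7102 of 10370 genes changed between BR100 and wild type (3805 higher, 3297 lower), 2663 of them by at least 2-fold. All 7102 had the same direction in both kits. The threshold ensured this, since disagreement between kits enters the error, so it is no separate support. The median SE of a fold change was 0.0876. Of 30 lists, 14 shifted (8 up, 6 down); with an estimated correlation 0 did (3 at unadjusted p under 0.05), and fry called 28. Adjusted over the list alone, the counts of changed genes were as above except for the unfolded protein response (3 higher, 14 lower) and the ribosome (1 higher, 0 lower). Without the kit block 4387 genes were called and the MHC class I and metallothionein calls were lost, and 11972 of 19055 probe sets were called when each was tested on its own. With the probe sets of a gene averaged, list medians were 0.62 for the 20S core, 0.35 for the respiratory chain and −0.48 for hypoxia, all still called. The ACTB gap moved with the variants in this comparison, at 4.22 in wild type against 3.03 in BR100 on Express arrays and 2.995 against 1.86 on One-Cycle arrays.

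**Figure D1:**
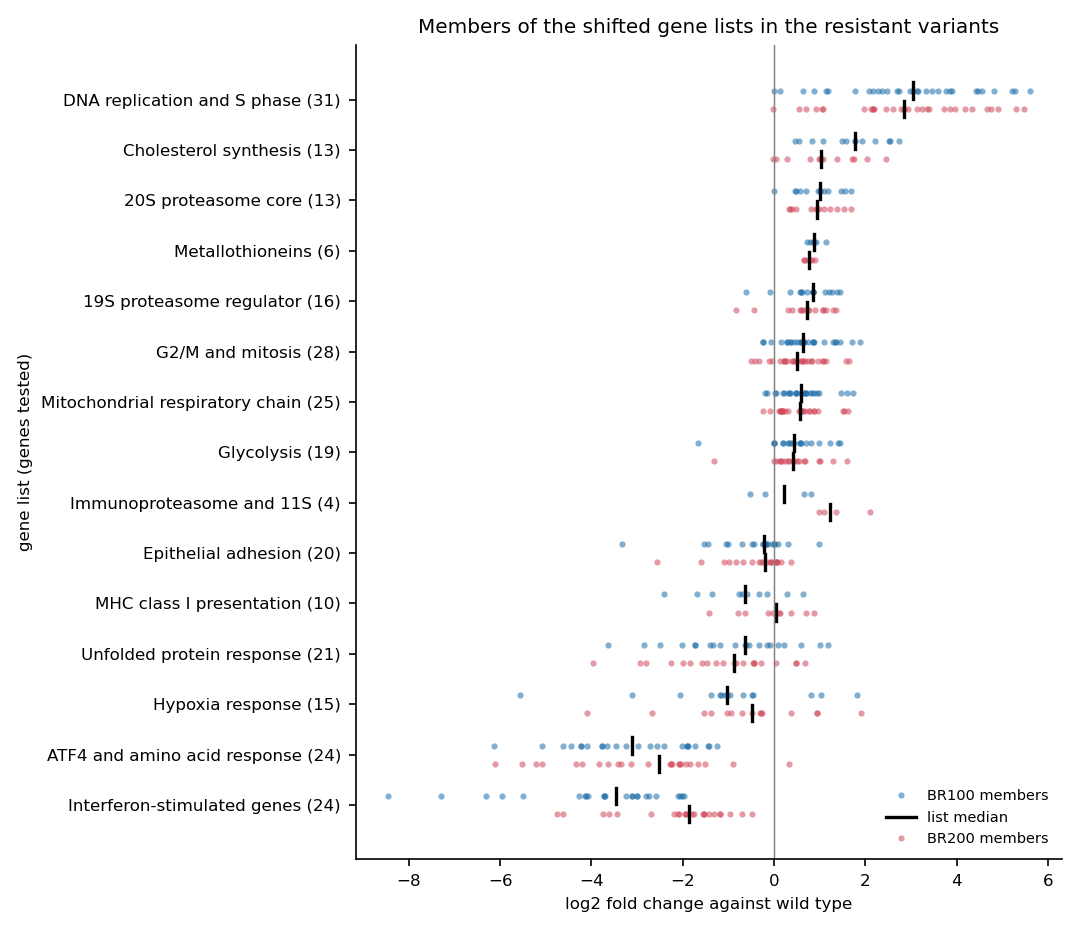
Each point is the log2 fold change of 1 gene against wild type (horizontal axis), with BR100 above and BR200 below for each list called shifted in at least 1 of these comparisons; black bars are list medians. Replication genes had the highest medians (3.04 and 2.85) and interferon-stimulated genes spread furthest down in BR100 (−8.46, a fall to near background).

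The second comparison set BR200 against wild type. The same groups stood out: proteasome subunits, replication genes and cholesterol synthesis genes were higher, and ATF4 and interferon-stimulated genes were lower. With an estimated correlation these lists lost their calls (adjusted p = 0.354 to 0.441). PSMB5 rose to 12.26 ± 0.22 (SD, n = 2), 3.24-fold above wild type (log2 change 1.69, SE 0.0664, adjusted p = 0.000193). In addition, the immunoproteasome subunits PSMB9 and PSMB8, which interferon induces, rose by 2.10 (SE 0.0857) and 1.10 (SE 0.0967).

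All 13 genes of the 20S core rose in BR200 (median 0.93, adjusted p = 0.000445 and adjusted p = 0.421 with an estimated correlation), PSMA3 by 1.52, PSMB2 by 1.38 and PSMB1 by 0.32. In the 19S regulator 14 of 16 rose and 2 fell (median 0.72, adjusted p = 0.00378 and adjusted p = 0.441 with an estimated correlation), with PSMC1 at 1.35 and PSMD2 at −0.84. All 4 immunoproteasome genes rose (median 1.23, adjusted p = 0.0173 and adjusted p = 0.426 with an estimated correlation). POMP changed by 0.39 and NFE2L1 by −1.85. The assembly list had 8 higher and 2 lower of 13 (median 0.39, adjusted p = 0.231), and the ubiquitin list 8 higher and 4 lower of 15 (median 0.26, adjusted p = 0.318). The ATF4 list fell in 23 of 24 (median −2.52, adjusted p = 2.42e-11 and adjusted p = 0.354 with an estimated correlation), CHAC1 by 6.11, DDIT4 by 5.52, SESN2 by 5.21, NUPR1 by 5.08 and DDIT3 by 3.63, and the exception was ATF3 at 0.33 (adjusted p = 0.275). Unfolded protein response genes fell in 16 of 21 and rose in 2 (median −0.88, adjusted p = 0.000479 and adjusted p = 0.354 with an estimated correlation), with ERN1 at −3.96, HERPUD1 at −2.95, XBP1 at −1.28 and HSPA5 at −1.12. Metallothioneins rose in 6 of 6 (median 0.76, adjusted p = 0.0134 and adjusted p = 0.421 with an estimated correlation). Heat shock genes again split 9 higher, 2 lower of 15 (median 0.47, adjusted p = 0.231), with HSPB1 at 2.64.

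Replication genes rose in 30 of 31 (median 2.85, adjusted p = 1.42e-11 and adjusted p = 0.354 with an estimated correlation), MCM10 by 5.47, POLE2 by 5.29 and CCNE2 by 4.90. G2/M genes rose in 18 of 28 and fell in 3 (median 0.50, adjusted p = 0.00327 and adjusted p = 0.441 with an estimated correlation). Cholesterol synthesis genes rose in 10 of 13 with none lower (median 1.03, adjusted p = 0.00102 and adjusted p = 0.354 with an estimated correlation), FDPS by 2.45 and HMGCS1 by 2.03. The respiratory chain list had 16 higher and 1 lower of 25 (median 0.56, adjusted p = 0.0012 and adjusted p = 0.354 with an estimated correlation), with NDUFB8 at 1.62 and NDUFA9 at 1.53. Glycolysis genes were higher in 12 of 19 and lower in 1 (median 0.41, adjusted p = 0.0159 and adjusted p = 0.441 with an estimated correlation), ALDOC at 1.61 and SLC2A1 at −1.31. Interferon-stimulated genes fell in 23 of 24 (median −1.86, adjusted p = 1.03e-09 and adjusted p = 0.421 with an estimated correlation), MX2 by 4.75, IFI44L by 4.63 and IFI6 by 3.74. Epithelial adhesion genes fell in 9 of 20 and rose in 1 (median −0.20, adjusted p = 0.04 and adjusted p = 0.441 with an estimated correlation), CLDN1 at −2.57 and ESRP1 at −1.60. The hypoxia list, with 10 lower and 4 higher of 15, was not past the threshold (median −0.48, adjusted p = 0.089).

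The other lists did not pass in BR200. They were MHC class I (3 higher, 3 lower of 10; median 0.05, mean −0.08, camera direction down, adjusted p = 0.899), NRF2 (8 higher, 6 lower of 18, adjusted p = 0.704) and autophagy (6 higher, 10 lower of 22; median 0.04, mean −0.35, camera direction down, adjusted p = 0.419). Cell death lists counted 1 higher and 4 lower of 10 anti-apoptotic genes (adjusted p = 0.155), 10 higher and 5 lower of 20 pro-apoptotic genes (adjusted p = 0.447), and 2 higher and 8 lower of 15 p53 targets (adjusted p = 0.128). MCL1 fell by 0.58 and PMAIP1 by 0.92. SQSTM1 and BCL2L1 were at −0.41 and −0.33, both past the threshold, but at 0.07 and 0.08 and not past it when their probe sets were averaged. Efflux transporters split 3 higher, 2 lower of 7 (adjusted p = 0.767), with ABCG2 at 2.22, and NF-kappaB targets 6 higher, 1 lower of 12 (adjusted p = 0.196), with CXCL8 at 3.96. Mesenchymal genes split 3 higher, 5 lower of 9 (median −0.47, mean 0.45, camera direction down, adjusted p = 0.77), with FN1 at 4.86. Enterocyte genes had 2 higher and 5 lower of 8 (adjusted p = 0.226), goblet genes 1 higher and 4 lower of 9 (adjusted p = 0.231), stem cell and Wnt genes 3 higher and 5 lower of 11 (adjusted p = 0.462), and ribosomal protein genes 3 higher and 1 lower of 22 (adjusted p = 0.697). Of the fibroblast markers ACTA2 rose by 1.13, and of the blood cell markers CD14 rose by 1.05.

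Among the genes that fell furthest in BR200 were TM4SF4 by 10.39 (SE 0.0664), UNC5B by 8.69 (SE 0.358), LAMP3 by 8.37 (SE 0.469), NIBAN1 by 8.29 (SE 0.150), CLGN by 8.22 (SE 0.0888) and INHBE, an inhibin subunit gene, by 7.01. All but NIBAN1 fell to near background, so their order depends on the background estimate; with values under 4 set to 4, TM4SF4 was at −8.63, NIBAN1 at −8.23, LAMP3 at −7.53, UNC5B at −7.31, CLGN at −6.58 and INHBE at −5.28. SLC26A9 rose by 6.16 (SE 0.119), SRPX2 by 5.66 (SE 0.0877), both from near background, and the kinase anchor gene AKAP12 by 5.62 (SE 0.209). limma called 6901 of 10370 genes changed (3668 higher, 3233 lower), 2457 by at least 2-fold. All had the same direction in both kits, which the threshold again ensured. Of 30 lists, 13 shifted (9 up, 4 down); with an estimated correlation 0 did (3 at unadjusted p under 0.05), and fry called 28. Adjusted over the list alone, counts differed from those above for the unfolded protein response (3 higher, 16 lower), interferon-stimulated genes (24 lower), hypoxia (4 higher, 11 lower), autophagy (7 higher, 10 lower), ubiquitin (9 higher, 4 lower) and the ribosome (2 higher, 0 lower). Without the kit block 4100 genes were called and the metallothionein and epithelial adhesion calls were lost, and 11349 of 19055 probe sets were called when each was tested on its own. With the probe sets of a gene averaged, list medians were 0.50 for the 20S core, 0.25 for the respiratory chain and −0.13 for epithelial adhesion, all still called; the epithelial call was also lost with quantile normalization, without BR200 replicate 2 and without wild type replicate 2. The ACTB gap was 4.22 in wild type against 3.24 in BR200 on Express arrays, and 2.995 against 1.76 on One-Cycle arrays.

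**Figure D2:**
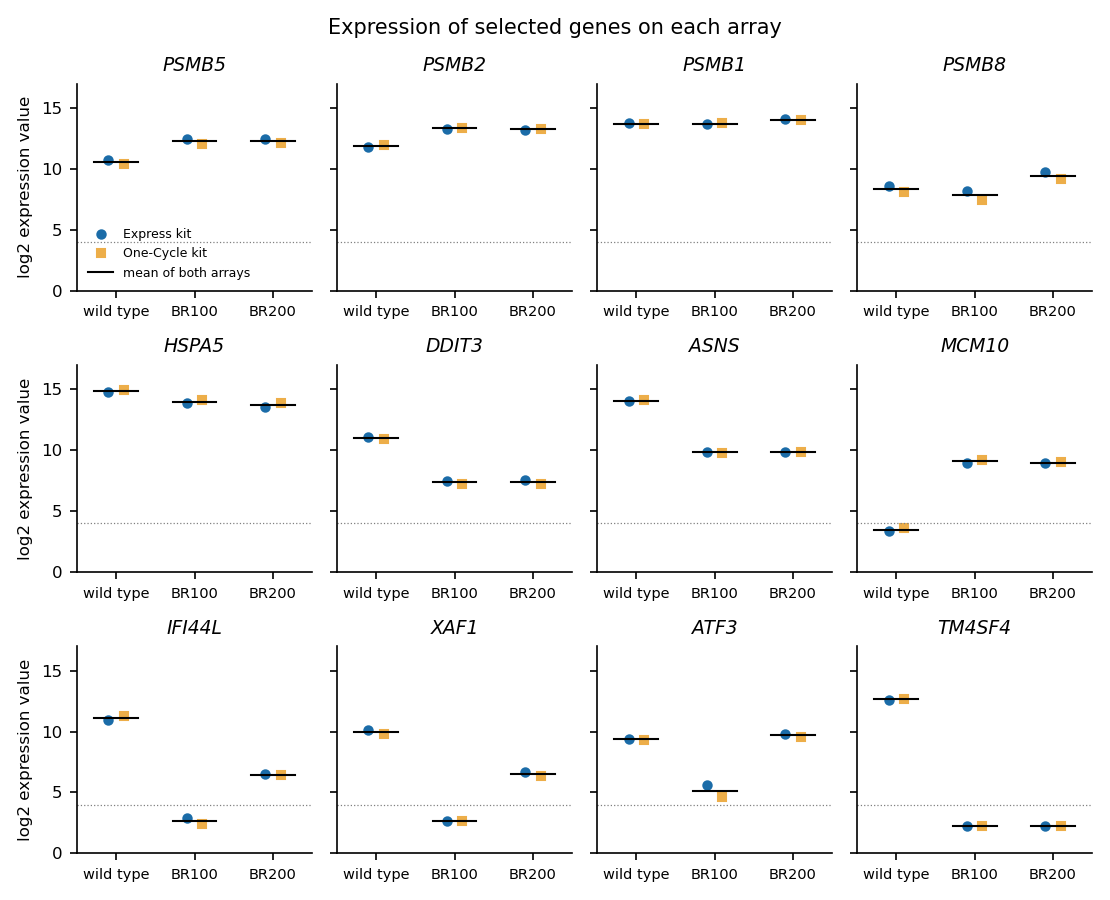
Log2 expression values (vertical axis) of 12 genes on each array by variant; circles are Express arrays, squares One-Cycle arrays, black bars the means of the 2 arrays, and the dotted line the filter at 4. PSMB5 stood at 10.57 in wild type and 12.26 in both resistant variants, while IFI44L fell by 8.46 in BR100, to near background, and by 4.63 in BR200.

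Changes were largely shared by the 2 resistant variants, which answers how alike they were relative to wild type. The same direction past the threshold was found for 6003 genes, 3222 higher and 2781 lower in both. Independent calls would give 1346 and 1028, but these calls share the wild-type arrays. SLC26A9, MCM10, PHACTR3, POLE2 and NUDT7 led the shared rises, and TM4SF4, UNC5B, LAMP3, NIBAN1 and CLGN the shared falls. Across genes the log2 changes correlated at r = 0.941 (0.933 within the Express kit and 0.937 within the One-Cycle kit), with a covariance of 1.20. Unchanged groups simulated against shared controls gave r = 0.502, a covariance of 0.00705 and 0 genes alike. That count was near certain with no gene changed, so it is no yardstick for the 6003. With the controls split, an alternative chosen after seeing the data, each resistant variant was set against a different wild-type array of its own kit. This gave r = 0.916 and 0.908, with covariances of 1.19 and 1.18. The labels do not say whether the wild-type arrays came from separate cultures, so part of the likeness may still come from a shared wild-type culture. They also give BR100 and BR200 the same course of rising doses before cloning, and do not say that the variants were derived independently. The likeness therefore cannot be read as that of independent derivations of resistance. Opposite directions were called for 48 genes, 36 of them higher in BR200. The count of genes alike was 3563 without the kit block, 2079 with a 2-fold minimum and 9856 for single probe sets.

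**Figure D3:**
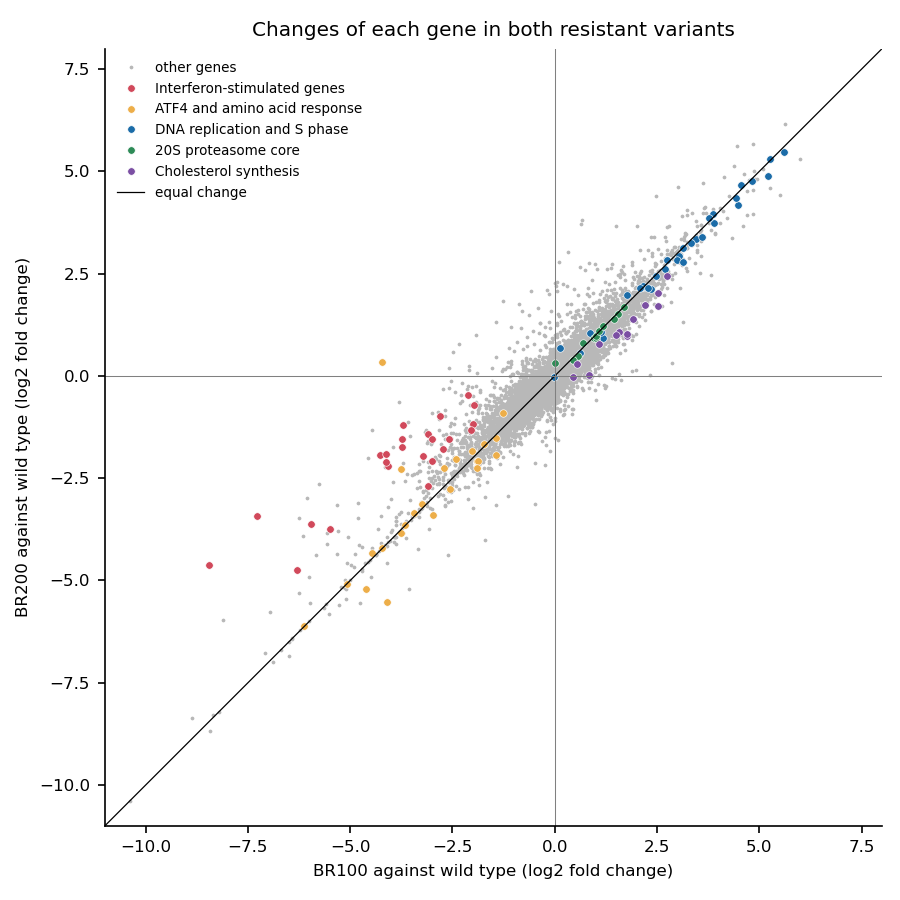
Log2 fold change of each gene against wild type in BR100 (horizontal axis) and BR200 (vertical axis), with 5 gene lists coloured and the line of equal change. Points lay along the line (r = 0.941), while interferon-stimulated genes lay above it (medians −3.47 and −1.86).

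The third comparison set BR200 against BR100 directly. Interferon-stimulated, immunoproteasome and MHC class I genes were higher in BR200, and cholesterol synthesis genes were lower. All 4 lists lost their calls with an estimated correlation (adjusted p = 0.319 for each). XAF1 and IFI44L, both interferon-stimulated, were higher by 3.86 (SE 0.102, adjusted p = 0.00283) and 3.83 (SE 0.204, adjusted p = 0.00525), each from near background in BR100. ATF3, a stress-induced transcription factor, was higher by 4.56 (SE 0.235), at 9.68 ± 0.14 in BR200, 5.12 ± 0.69 in BR100 and 9.35 ± 0.10 in wild type (SD, n = 2 each). The ACTB gap was close in both variants, 3.03 and 1.86 in BR100 against 3.24 and 1.76 in BR200. Of markers of other cell types, TAGLN (fibroblast) was higher in BR200 by 1.32, from near background, and CD14 (blood cell) by 0.78, while ACTA2 at 0.11, COL1A1 at 0.13, LYZ at 0.0726 and ENG (endothelium) at −0.0244 did not pass.

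Of 24 interferon-stimulated genes, 22 were higher in BR200 than in BR100 and 24 adjusted over the list alone (median 1.72, adjusted p = 1.06e-21 and adjusted p = 0.319 with an estimated correlation), including IFI35 at 2.51 and MX1 at 2.36. Immunoproteasome genes were higher in 3 of 4 (median 1.17, adjusted p = 0.000409 and adjusted p = 0.319 with an estimated correlation), PSMB9 by 2.30, PSMB8 by 1.62 and PSMB10 by 0.70. MHC class I genes were higher in 8 of 10, or 10 adjusted over the list alone (median 0.62, adjusted p = 2.3e-07 and adjusted p = 0.319 with an estimated correlation), with TAP2 at 0.99 and HLA-C at 0.92. In the cholesterol list 10 of 13 were lower, or 12 adjusted over the list alone (median −0.50, adjusted p = 1.95e-07 and adjusted p = 0.319 with an estimated correlation), INSIG1 by −0.82, SC5D by −0.80 and DHCR7 by −0.79. Hypoxia genes were higher in 4 of 15, or 7 adjusted over the list alone (median 0.31, adjusted p = 0.000902 and adjusted p = 0.319 with an estimated correlation), with NDRG1 at 1.45 and ANKRD37 at 1.44; the median was 0.16 without the filter and 0.18 with probe sets averaged. Autophagy genes were higher in 5 of 22, or 6 adjusted over the list alone (median 0.24, adjusted p = 0.000894 and adjusted p = 0.541 with an estimated correlation), with WIPI1 at 0.83 and SQSTM1 at 0.66. The unfolded protein response list was lower (median −0.26, adjusted p = 0.000894 and adjusted p = 0.319 with an estimated correlation) with 1 of 21 genes past the threshold, PDIA4 at −0.50, or 8 adjusted over the list alone.

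Smaller list shifts had few called members. G2/M genes were lower in 4 of 28, or 4 lower and 1 higher adjusted over the list alone (median −0.17, adjusted p = 0.000894 and adjusted p = 0.541 with an estimated correlation, adjusted p = 0.0507 by fry), MKI67 by −0.70 and CENPE by −0.56. Heat shock genes counted 1 lower of 15, HSPB1 at −0.58, and 0 adjusted over the list alone (median −0.17, adjusted p = 0.0254 and adjusted p = 0.421 with an estimated correlation). NRF2 genes were higher in 5 of 18 by either adjustment (median 0.10, adjusted p = 0.0289 and adjusted p = 0.421 with an estimated correlation); AKR1C1, AKR1C3, AKR1C2 and AKR1B10 stood at 2.42, 2.24, 1.98 and 1.36. The NRF2 call was lost without the filter (adjusted p = 0.0971), with values under 4 set to 4 (0.0728), with probe sets averaged (0.094, median −0.00687), and without BR100 replicate 2 (0.0643, median 0.0617), BR200 replicate 2 (0.131, median 0.0657) or either wild-type array (0.0615). Enterocyte genes were higher in 2 of 8, or 4 adjusted over the list alone (median 0.28, adjusted p = 0.0196 and adjusted p = 0.541 with an estimated correlation), CEACAM6 by 0.88 and DPP4 by 0.47. The enterocyte call was lost without BR100 replicate 1 (adjusted p = 0.0747, median 0.13) and without the filter (adjusted p = 0.175), and the heat shock call without the kit block, BR100 replicate 1 or BR200 replicate 1. Proteasome subunits of the 20S core and 19S regulator differed in 0 of 13 and 0 of 16 genes by limma, with medians of −0.03 (adjusted p = 0.97) and −0.10 (adjusted p = 0.0873), and PSMB5 differed by 0.01 (SE 0.0664). The replication list had 1 gene higher, E2F1 at 0.55, and none adjusted over the list alone (adjusted p = 0.548). The ATF4 list had 4 higher and 3 lower of 24 (adjusted p = 0.916), with PPP1R15A at 1.48 and DDIT4 at −1.42.

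The remaining lists tested with camera were not called shifted between BR200 and BR100. Pro-apoptotic genes had 6 of 20 higher (adjusted p = 0.0873), TNFSF10 by 3.07, BIK by 1.27 and PMAIP1 by 1.25, and anti-apoptotic genes 1 of 10, BCL2L1 by 0.52 (adjusted p = 0.837). p53 targets counted 3 higher and 1 lower of 15 (adjusted p = 0.25), TP53INP1 at 1.37; NF-kappaB targets 2 higher and 1 lower of 12 (adjusted p = 0.502), CXCL2 at 2.78. Mesenchymal genes had 3 of 9 higher (median −0.15, mean 0.39, camera direction up, adjusted p = 0.837), TNC by 2.46 and S100A4 by 1.83. Efflux transporters had 1 higher and 1 lower of 7 (adjusted p = 0.202), epithelial adhesion genes 2 higher and 1 lower of 20 (adjusted p = 0.154), with CLDN2 at −1.31, and stem cell and Wnt genes 1 higher and 2 lower of 11 (adjusted p = 0.117). Glycolysis counted 1 higher and 1 lower of 19 (adjusted p = 0.586) and ubiquitin 1 lower of 15 (median 0.03, mean −0.05, camera direction down, adjusted p = 0.778). By limma, 0 genes passed in the assembly (adjusted p = 0.607), goblet (adjusted p = 0.685), respiratory chain (adjusted p = 0.417), ribosome (adjusted p = 0.928) and metallothionein (adjusted p = 0.189) lists. Adjusted over the list alone, counts higher and lower differed for goblet (1 and 3), epithelial adhesion (5 and 3), NF-kappaB (5 and 2), ATF4 (5 and 5), p53 (4 and 1), mesenchymal (3 and 2), efflux (2 and 1), stem cell and Wnt (1 and 4) and anti-apoptotic genes (1 and 1).

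Other genes higher in BR200 than in BR100 were CCN2 by 3.18, VNN1 by 3.15, ECI2 by 3.15 and DNAJC15 by 3.13, each from near background, and GBP1, an interferon-induced GTPase gene, by 3.12 (SE 0.0983). IQGAP2 was lower by a log2 change of −2.63 (SE 0.153), DNM3 of −2.56 (SE 0.145) and ONECUT2 of −2.33 (SE 0.129). limma called 1102 of 10370 genes different (663 higher and 439 lower in BR200), 248 by at least 2-fold. All had the same direction in both kits, which the threshold ensured here too. Of 30 lists, 11 shifted (7 up, 4 down); with an estimated correlation 0 did (3 at unadjusted p under 0.05), and fry called 14. The gene count rested on having all 6 arrays: without either BR100 array or either BR200 array limma called 0 genes (1953 to 2135 at unadjusted p under 0.05, where 518.5 are expected by chance), and without either wild-type array 61. It was 112 without the kit block, 15 without the filter, and 1745 with an intensity trend.

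The technical comparison asked how far the kits differed on the same variants. Each kit went with its own RNA input (100 ng for Express and 3 ug for One-Cycle), so kit and input cannot be told apart. A difference in culture between the arrays of a variant cannot be told apart from them either, as the labels do not say whether the cultures were separate. limma called 3530 genes different, 2318 higher with the Express kit and 1212 with the One-Cycle kit, and 309 differed by at least 2-fold. The excess for Express depended on scaling: the split was 1820 and 1758 with quantile normalization, and 1627 and 2127 with median centring. Chosen after the values were seen, the largest differences were MIX23 at 5.48 and TAF15 at 2.88, higher with Express, and EPHX1 at −3.38, PLK1 at −3.30 and PKM at −3.06, higher with One-Cycle. The control probe set for 18S ribosomal RNA read 13.73 to 14.68 on Express arrays and 8.32 to 8.59 on One-Cycle arrays. Leaving out any single array lowered the gene count, to 430 without a BR200 array, 591 without a BR100 array and 1797 without a wild-type array. Without the variant block it was 59, and without the filter 468.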

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

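Tests of chromosome 14, of wild-type cells in BR200, of fewer dividing cells, of RNA quality for the ATF4 genes and of bortezomib in the wild-type culture were chosen after the results they address had been seen. The 2 tests of normalization and that of RNA quality for the replication genes were written before. Bootstrap intervals in this part come from resampling the genes of a list. Such genes are not independent replicates, so the intervals do not measure the spread between arrays or cultures.

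Differences between the resistant variants drew attention because limma or camera called the difference itself, although every list call was lost with an estimated correlation (adjusted p = 0.319 to 0.541). In opposite directions against wild type stood 48 genes. List medians of BR200 minus BR100 were 1.72 for interferon-stimulated genes, 1.17 for the immunoproteasome, 0.62 for MHC class I, 0.31 for hypoxia, 0.28 for enterocyte, 0.24 for autophagy and 0.10 for NRF2 genes. They were −0.17 for heat shock, −0.17 for G2/M, −0.26 for the unfolded protein response and −0.50 for cholesterol synthesis. Single genes higher in BR200 were GBP1 at 3.12, SYT13 at 3.10, TNFSF10 at 3.07, PSMB8 at 1.62, ANKRD37 at 1.44, PMAIP1 at 1.25, SRPX2 at 0.80, SQSTM1 at 0.66 and BCL2L1 at 0.52, and those lower were CLDN2 at −1.31 and PHACTR3 at −0.71. Without any 1 of the 4 BR100 and BR200 arrays, limma called 0 genes between these variants (1953 to 2135 at unadjusted p under 0.05), and without a wild-type array 61.

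Interferon-stimulated genes were higher in BR200 than in BR100 by a median of 1.72 over 24 genes. Wild-type cells mixed into BR200 would return other genes to the same extent, but 86 other genes at least 16-fold lower in BR100 than in wild type allowed a median share of 0.0942% (95% bootstrap interval 0.0161 to 0.623), against 21.4% (16.2 to 25.2) from the interferon genes. A normalization trend with signal level is argued against too, since random lists of the same size and signal reached at most 0.198. A difference between the clones themselves is a hypothesis that these data leave open, as is a difference in culture or in drug at harvest, which was not tested.

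Proteasome subunits of the 20S and 19S lists were higher in both resistant variants, with a median of 0.85 in BR100 and 0.81 in BR200 over 29 genes. Extra copies of chromosome 14, which holds 4 of them, could not be the whole cause, since the 25 genes elsewhere had a median of 0.852 (0.578 to 1.005) in BR100 and 0.749 (0.483 to 0.930) in BR200. Random lists of the same size and signal reached at most 0.594 in BR100 and 0.612 in BR200, which argues against a normalization trend. The resistant state remains a candidate explanation, untested beside drug present at harvest.

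Replication genes were higher and ATF4 genes lower in both resistant variants. Fewer dividing cells in the wild-type culture stay open. The replication median exceeded the G2/M median by 2.41 (1.70 to 2.99) in BR100 and 2.35 (1.68 to 3.01) in BR200. That gap would argue against this cause only if it moved both lists equally, which was assumed and not shown. G2/M genes were themselves higher than in wild type, by medians of 0.64 in BR100 and 0.50 in BR200. Lower RNA quality in wild type stays open: replication genes differed by a median of −0.0535 (−0.138 to 0.0838) between kits whose ACTB gap differed by 1.29, but the GAPDH gap differed by 0.0614 between kits and by 0.250 between wild type and the resistant variants, so (a condition added after the result was seen) the kits do not stand in for the variants, and the ATF4 median of −3.10 (−3.76 to −2.02) is the pattern itself and decides nothing. Bortezomib in the wild-type culture cannot be told apart from a difference between the cells: heat shock genes, which it would raise, had a median of 0.63 (0.04 to 0.79) in BR100 but an interval reaching below zero in BR200 (0.47, −0.17 to 0.56). These medians also lack HSPA1A, HSPA1B and HSPA8, which had no probe set of their own. Density and nutrients of the wild-type culture also stay open, since they go with the variant.

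Probe sets that name no gene or several genes were outside the gene tests. Among 3320 of them above the filter, 81 were near background in wild type, and 40 of these were higher in both resistant variants, 30 by at least 2-fold in both. Those 81 had passed the filter only through arrays of the resistant variants. Their selection therefore favoured a rise there, and the counts are no evidence of an excess of risers.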

How the results depend on the processing

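The alternatives were planned, except the split of the controls, which was chosen after seeing the data. Camera's direction did not change for any of the 38 list calls, though the NRF2 median between BR200 and BR100 was −0.00687 with probe sets averaged, and all-gene medians moved by less than 0.1, except for the kits with median centring (by −0.107), where 1627 genes were higher with Express and 2127 with One-Cycle, against 2318 and 1212. The genes changed numbered 4387 (BR100 against wild type), 4100 (BR200 against wild type), 112 (BR200 against BR100) and 3563 (alike in both) without the kit block, and 2663, 2457, 248 and 2079 with a 2-fold minimum, which left 309 for the kits. Each probe set on its own gave 11972, 11349 and 9856 alike, 6713 for the kits and r = 0.933, from more units tested. BR200 against BR100 gave 15 without the filter, 1745 with an intensity trend and 61 with only those variants fitted, and the kits gave 468 without the filter and 59 without the variant block. The degrees of freedom added by eBayes were 0.356 without the filter and 3.41 with an intensity trend, against 2.33 in the main fit. Fitting only the compared variants left fewer residual degrees of freedom. Without the variant block, differences between variants entered the error. How far each of these moved the counts was not tested. The r between the resistant variants was 0.945 with the filter at 6, and 0.916 and 0.908 with the controls split, where each side rests on 1 array per variant. Shifted lists numbered 0, 0 and 0 with an estimated correlation (3 each at unadjusted p under 0.05), and 28, 28 and 14 by fry, which tests another question. Leaving out each array in turn, with a lone array assumed to vary like the others, gave 5540 to 6606, 5162 to 6457 and 0 to 61 genes for the 3 comparisons, 4711 to 5139 alike, 430 to 1797 for the kits, r of 0.933 to 0.943, and 14 to 15, 12 to 13 and 9 to 10 lists. The counts of 0 came without any BR100 or BR200 array, with smallest adjusted p of 0.0508 to 0.0714 and fewer residual degrees of freedom. With probe sets averaged, list medians in BR100 and BR200 were 0.62 and 0.50 for the 20S core and 0.35 and 0.25 for the respiratory chain, hypoxia was at −0.48 in BR100 and epithelial adhesion at −0.13 in BR200, all still called, while SQSTM1 and BCL2L1 in BR200 were at 0.0694 and 0.0825 and MCL1 in BR100 at 0.20; without cross-hybridizing or shared probe sets PSMD11 in BR100 was at −0.12 and SDHC at −0.37 in BR100 and −0.10 in BR200, other probe sets having been read. Of 38 list calls, 5 were lost without the kit block: MHC class I and metallothioneins in BR100, epithelial adhesion and metallothioneins in BR200, and heat shock between BR200 and BR100. With an estimated correlation all 38 were lost, which the 2 residual degrees of freedom of that test made likely whatever the correlation. Other losses in BR200 were epithelial adhesion with quantile normalization, without BR200 replicate 2 and without wild type replicate 2. Between BR200 and BR100, NRF2 was lost without the filter, with values under 4 set to 4, with probe sets averaged, and without BR100 replicate 2, BR200 replicate 2 or either wild-type array, enterocyte without the filter and without BR100 replicate 1, heat shock without BR100 replicate 1 or BR200 replicate 1, and G2/M by fry. Of 379 named gene results, 96 lost their call without the kit block, 94 without the filter, 74 with only the compared variants fitted, 91 and 92 without a BR100 array, 97 and 98 without a BR200 array, and 76 and 80 without a wild-type array. So did 20 of 365 with probe sets averaged, 19 of 246 without cross-hybridizing or shared probe sets, and 0 to 5 under each other alternative but the 2-fold minimum, which was not applied to single genes. With each kit alone, which gives no test, 87 of 379 moved past their error and 0 changed direction. The absence of a change in direction followed from the threshold these genes had passed. Values near the lowest value of 2.23 limit folds of genes near background.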

Other observations

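All tests in this part were chosen after the values had been seen, except the count of other splits for the kits. Most mitochondrial ribosome genes, which no list had covered, were called higher in both resistant variants. Of 49 MRPL genes, 39 rose and 1 fell in BR100 (median 0.89, camera adjusted p = 1.78e-06 over 68 symbol families, and adjusted p = 0.814 with an estimated correlation), and 40 rose and 1 fell in BR200 (median 0.70, adjusted p = 1.85e-05 and adjusted p = 0.805); MRPL9 stood at 1.70 and 1.49, and MRPL37 at 1.61 and 1.40. Of 27 MRPS genes, 23 rose and 1 fell in BR100 (median 0.70, adjusted p = 0.000219 and adjusted p = 0.814 with an estimated correlation), and 22 rose and 1 fell in BR200 (median 0.77, adjusted p = 0.000479 and adjusted p = 0.805), with MRPS27 at 1.65 and 1.53. Of 55 RNF genes, 37 fell and 7 rose in BR100 (median −0.51, adjusted p = 0.00139 and adjusted p = 0.814 with an estimated correlation), and 33 fell and 6 rose in BR200 (median −0.41, adjusted p = 0.00168 and adjusted p = 0.805). The other families called were NUP in BR100 (16 higher, 2 lower of 22; median 0.65, adjusted p = 0.0451), ZNF in BR200 (52 higher, 121 lower of 289, median −0.20, adjusted p = 0.0165) and MRPL between BR200 and BR100 (0 higher and 1 lower by limma, median −0.12, adjusted p = 0.0251). These 3 calls were lost as well (adjusted p = 0.814, 0.805 and 0.994).

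Medians of some chromosome regions stood apart from those of shuffled positions. On chromosome 14, 349 genes had a median of 0.63 in BR100 and 0.66 in BR200, with 79.1% and 83.4% of them higher, where 10000 shuffles of gene positions gave at most 0.26 and 0.21. Past all shuffles, with medians smaller in size, were also chromosome 3 (median −0.0857 in BR100 and −0.0743 in BR200) and chromosomes 8 and 11 in BR200 (−0.14 and −0.21). Between BR200 and BR100 they were chromosomes 11 (−0.18 over 614 genes, 24.3% of them higher), 19 (−0.0668), 6 (0.0484) and 15 (0.0668). For chromosome 11 between these variants, shuffles reached no lower than −0.0606. A gain along the whole of chromosome 14 may account for its median, but it could not be settled: of 11 successive blocks of 30 genes and a last block of 19, the lowest median was 0.335 in BR100, above a bar of 0.30 from other chromosomes, and 0.25 in BR200, below a bar of 0.26. On chromosome 3, 30 neighbouring genes from YEATS2 to IL1RAP had a median of −1.54 in BR100 and −1.45 in BR200, with 26 and 27 called lower, PSMD2, CLDN1 and DNAJB11 among them. In 100 shuffles of gene positions, windows of 30 genes reached no lower than −0.81 and −0.73. A local loss stays a hypothesis, as DNA was not measured. The windows on chromosomes X, 6 and 15 below were also set against 100 shuffles. On the X chromosome, 30 genes from PGK1 to MORF4L2 had medians of 1.25 and 1.66, past shuffled extremes of 0.88 and 0.81, but only 20 of 30 (19 called) and 19 of 30 (18 called) were higher. Between BR200 and BR100, 30 genes from STX7 to PEX3 on chromosome 6 were all higher in BR200 (median 0.44, 14 called, shuffled extreme 0.32), VNN1 among them, and 30 genes from NGRN to SELENOS on chromosome 15 had a median of −0.39 (24 of 30 lower, 10 called, shuffled extreme −0.29).

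Fitted without the variant block, the split of the arrays by kit gave 59 genes and the highest other split 0, so 1 of 10 splits reached the real count; 10 splits are too few to give a share under 0.05.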
